A study of Mus musculus with 9 samples.

How the data were processed

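Poly(A) RNA of naive CD4+ T cells from mouse spleen was measured in 9 libraries, 3 each from untreated mice, mice given an antibody against IL-1b for 10 days and mice given MCC950 for 10 days. Per the labels' protocols, RNA was extracted with RNAiso PLUS, cleaned on NucleoSpin columns and made into libraries with the NEBNext Ultra II Directional kit. The labels give no sort or gate, sex, batch or mouse of origin for any library. Samples were grouped by these labels alone.

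The authors aligned and quantified the reads with STAR and RSEM against the mm10 build, per the submitters' processing notes, which give no versions. The deposited expected counts are RSEM's estimates of reads per gene, not normalized, in which a read that matches several genes is shared between them, per the file headers. The deposited TPM values are transcripts relative to effective length, scaled by RSEM to one common total per library, per the file headers. The deposited FPKM values relate fragments to effective length and mapped depth, per the file headers, and entered only as a sum per library, at means of 705358, 687543 and 715496 in the untreated, anti-IL-1b and MCC950 groups. The deposited effective lengths are transcript lengths less the mean fragment length, per the file headers. Whether the counting used strand is not given in the sources used here, so values of genes with an antisense partner are uncertain. Values of genes with near-identical copies are uncertain as well, among them beta-globin, Xlr3b, Hspd1, Hspe1 and ribosomal protein genes.

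All 55487 gene IDs were looked up in the GENCODE M21 annotation, whose GRCm38 build is the same as mm10, and 99.4% had a symbol. The 346 others held at most 0.0452% of the counts of a library. Total expected counts per library ran from 14775375 to 21394797, and TMM factors from 0.945 to 0.947 in the untreated group, from 1.031 to 1.035 in the anti-IL-1b group and from 1.023 to 1.024 in the MCC950 group. At least 99.9% of the counts of each library lay in tested genes.

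Expected counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit), after TMM scaling and edgeR's filterByExpr, which left 13374 genes. All p-values for genes are two-sided and were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. A fit of 3 group means over the 9 libraries gave 3 comparisons, anti-IL-1b against untreated, MCC950 against untreated and anti-IL-1b against MCC950. A fit of 2 means gave either inhibitor against untreated. The common biological coefficient of variation was 0.0707. Gene lists, 36 in all, were fixed with the comparisons, tests and named-gene rule before the data were examined. The 32 lists with at least 5 tested genes were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of these, 22 hold biology, and the others hold markers of other cells or signs of sample quality. For genes at 0 in the untreated group, bounds on the fold were set against 3 counts over the group.

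Named genes followed a fixed rule. For each inhibitor against untreated these were the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and all 3 treated libraries beyond all 3 untreated ones. For the other 2 comparisons they were the 5 largest rises and 5 largest falls by the same rule. Up to 4 members with the smallest p were named from each biology list that passed, and at most 1 past the threshold from every other list. Fixed checks included Cd4, Cd8a, Cd44, Ccr7, Il7r, Foxp3, Tbx21, Gata3, Il1r1, Il1b, Nlrp3 and Casp1. Of the genes that the rule names, 4 are not reported here and none took their place, while the tests of lists kept all members. Predicted genes, immunoglobulin and T cell receptor segments and pseudogenes were counted, not named. Before the last named gene, 3 such genes were passed over among the rises and 4 among the falls with the antibody, 4 and 3 with MCC950, 0 and 8 between the agents, and 3 and 3 for either inhibitor.

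The tests were run on simulated counts with known changes. At a fold of 1.2 the test recovered 25.5% of changed genes for anti-IL-1b against untreated, 28.6% for MCC950 against untreated, 31.5% between the agents (12730 genes each) and 31.9% for either inhibitor (12707 genes). At a fold of 2 it recovered 74.0%, 79.2%, 78.1% and 85.7%. Among unchanged genes it called 6 of 12539, 7 of 12540, 22 of 12355 and 11 of 12517.

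Alternatives were RLE, upper-quartile and library-total scaling, a filter of 1 count and one of CPM of at least 1 in at least 3 samples, DESeq2's Wald test (DESeq2 1.42.0), limma-voom, limma-trend on log2(TPM + 1), the replicate number as a block, a fit without the robust option, a threshold of 0.10, fits of each comparison on its own 6 samples, an averaged contrast of 3 means, a log2 fold change of at least 1, and leaving out each library in turn. Alternatives chosen after seeing the data were removal of GC and length trends (loess span 0.3, values for 13356 genes), edgeR's test against a fold change of 1.5, division of counts by the variance-to-mean factor of 3.87, and removal of stress genes from other lists.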

Results

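Poly(A) RNA was sequenced from naive CD4+ T cells, the helper T cells that have not yet met their antigen, of the spleens of wild-type C57BL6/J mice. The 9 libraries formed 3 groups of 3: cells of untreated mice, cells of mice given a neutralizing antibody against IL-1b for 10 days, and cells of mice given MCC950 for 10 days. IL-1b is an inflammatory cytokine. MCC950 is a small molecule that inhibits NLRP3, the sensor of the inflammasome that leads to the release of mature IL-1b. The series addresses what blocking IL-1b by either route does to these cells. Total expected counts per library ran from 17335367 to 21394797 in the untreated group, from 14775375 to 16676626 in the anti-IL-1b group and from 16769960 to 18497827 in the MCC950 group. Genes with at least 1 count numbered 16853 ± 70.8 per untreated library, 17433 ± 110 per anti-IL-1b library and 17428 ± 59.3 per MCC950 library (SD, n = 3). Nothing in the labels says that the 3 libraries of a group came from separate mice, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as CPM, the counts relative to each library's TMM-scaled total, as mean ± SD of 3 libraries. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13374 genes. Coordinates are those of the mm10 build.

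The transcripts that define the cells were abundant in all 3 groups. Cd4, the co-receptor gene of helper T cells (chromosome 6, 124864692 to 124888221), stood at 850 ± 9.73 CPM in untreated cells, 903 ± 6.98 with the antibody and 823 ± 5.25 with MCC950. Ccr7, the chemokine receptor gene of naive T cells, stood at 652 ± 12.4, 462 ± 6.92 and 444 ± 3.70 CPM. Il7r, the receptor gene of the survival cytokine IL-7, stood at 585 ± 10.8, 649 ± 32.3 and 561 ± 17.5 CPM. Cd44, a gene raised in antigen-experienced T cells, stood at 27.3 ± 0.972, 24.5 ± 1.43 and 22.2 ± 2.83 CPM. The lineage factors of regulatory and type 1 helper cells were near the lower limit of detection: Foxp3 lay at 0.543 ± 0.327, 1.14 ± 0.573 and 1.57 ± 0.680 CPM and Tbx21 at 0.397 ± 0.344, 0.345 ± 0.251 and 0.700 ± 0.132 CPM. Cd8a, the co-receptor gene of cytotoxic T cells, was at 0.970 ± 0.270 CPM in untreated cells and at 19.4 ± 2.69 and 19.7 ± 1.07 CPM in the antibody and MCC950 groups. Cd8b1, the gene of the other chain of that co-receptor, was not a fixed check. It was at 12.5 ± 1.83, 26.2 ± 0.764 and 23.0 ± 1.68 CPM, a smaller rise from a higher untreated level.

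Transcripts of Il1b, Nlrp3 and Il1r1 were scarce. Il1b (chromosome 2, 129364570 to 129371139) had 0 counts in the 3 untreated libraries. It had 6.18 ± 1.46 CPM with the antibody and 2.38 ± 0.564 CPM with MCC950. These levels are 115-fold and 44.3-fold higher than the floor of 3 counts over the untreated group. That floor covers the counting error of independent reads only. The variance-to-mean factor of untreated genes with 10 to 100 counts was 4.29, so such bounds may be too high. Neutrophil and granulocyte markers were higher in the same groups, with 9 of 10 tested members past the threshold with the antibody and 8 of 10 with MCC950, among them Csf3r at 0.0679 ± 0.0588, 6.09 ± 1.08 and 3.92 ± 1.06 CPM in the untreated, anti-IL-1b and MCC950 groups. Nlrp3, the target of MCC950, summed to 0 counts over the untreated, 42 over the anti-IL-1b and 18 over the MCC950 libraries, and Il1r1, the signalling receptor of IL-1, to 0, 4 and 7 counts. Both genes were too low to test. Casp1, the protease gene of the inflammasome, fell from 6.0 ± 1.48 to 3.21 ± 0.609 CPM with the antibody and to 1.75 ± 0.193 CPM with MCC950.

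Naive CD4+ T cell libraries of antibody-treated mice had fewer transcripts of the T cell receptor response, NF-kB response and heat shock lists than untreated ones. They had more transcripts of markers of B cells, cytotoxic cells and neutrophils, and which cells these came from was not tested. Fos, which encodes a subunit of the AP-1 transcription factor (chromosome 12, 85473890 to 85477273), fell from 1117 ± 6.25 to 205 ± 2.75 CPM, a log2 fold change of -2.45 ± 0.03 (SE, adjusted p = 9.00e-41). Tnfaip3, a feedback inhibitor of NF-kB (chromosome 10, 19000910 to 19015657), fell from 1387 ± 0.679 to 93.9 ± 3.82 CPM, a log2 fold change of -3.89 ± 0.03 (adjusted p = 2.73e-45). Hsph1, a heat shock chaperone gene (chromosome 5, 149614287 to 149636376), fell from 1168 ± 9.66 to 126 ± 3.47 CPM. All 3 antibody libraries lay below all 3 untreated ones for each of these genes. In all, 4545 of 13374 genes passed an adjusted p of 0.05, 2066 higher and 2479 lower with the antibody, and 818 of them differed at least 2-fold. Upper-quartile scaling turned this split into 2687 higher and 1941 lower, scaling to library totals alone into 3929 and 1344, and the TPM values into 2645 and 865. Library totals moved the median log2 fold change of all genes by 0.13 relative to TMM, so that small changes of either sign depended on the scaling.

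The largest falls with the antibody among named genes with a mean log2 CPM of at least 2 included those of Maff, Bambi and Sik1. Maff, a small basic leucine zipper gene (chromosome 15, 79346621 to 79359076), fell by 4.96 on the log2 scale, from 79.6 ± 6.63 to 2.58 ± 0.988 CPM. Bambi, a decoy receptor gene of the TGF-beta family, fell by 4.93, and Sik1, which encodes a salt-inducible kinase (chromosome 17, 31844250 to 31855804), fell by 4.39, from 437 ± 19.1 to 20.8 ± 0.666 CPM. Gem, Rgs1, Fosl2, Dusp4 and Nr4a2 had log2 fold changes of -4.21, -4.17, -4.11, -4.08 and -4.07. Of the 25 tested members of the T cell receptor response list, 17 fell and 4 rose, with a median log2 fold change of -1.20 (17 and 4 adjusted over the list alone; camera adjusted p = 1.26e-14). Nr4a1, an orphan nuclear receptor gene that tracks receptor signalling, fell from 963 ± 14.8 to 72.1 ± 2.35 CPM. Jun fell from 1618 ± 9.78 to 206 ± 8.29 CPM and Fosb from 687 ± 16.2 to 46.0 ± 0.278 CPM. Tnfrsf9, a costimulatory receptor gene on the same list, rose from 0.868 ± 0.621 to 6.25 ± 0.962 CPM. The NF-kB list fell as well, with 14 of 19 members lower, none higher and a median of -0.28 (14 adjusted over the list alone; camera adjusted p = 5.55e-08). Nfkbid, Nfkbiz and Nfkbia, which encode NF-kB regulators of the IkB family, had log2 fold changes of -2.26, -1.34 and -1.33. All 22 members of the list of heat shock and handling stress genes fell, with a median of -1.98 (22 adjusted over the list alone; camera adjusted p = 2.52e-53). Of these genes 6 are also on the T cell receptor response list, which without them kept an adjusted p of 1.86e-05 from camera. Taking out shared members cannot tell whether the others fell for the same reason. The labels do not say whether the groups were handled alike before lysis.

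**Figure D1:**
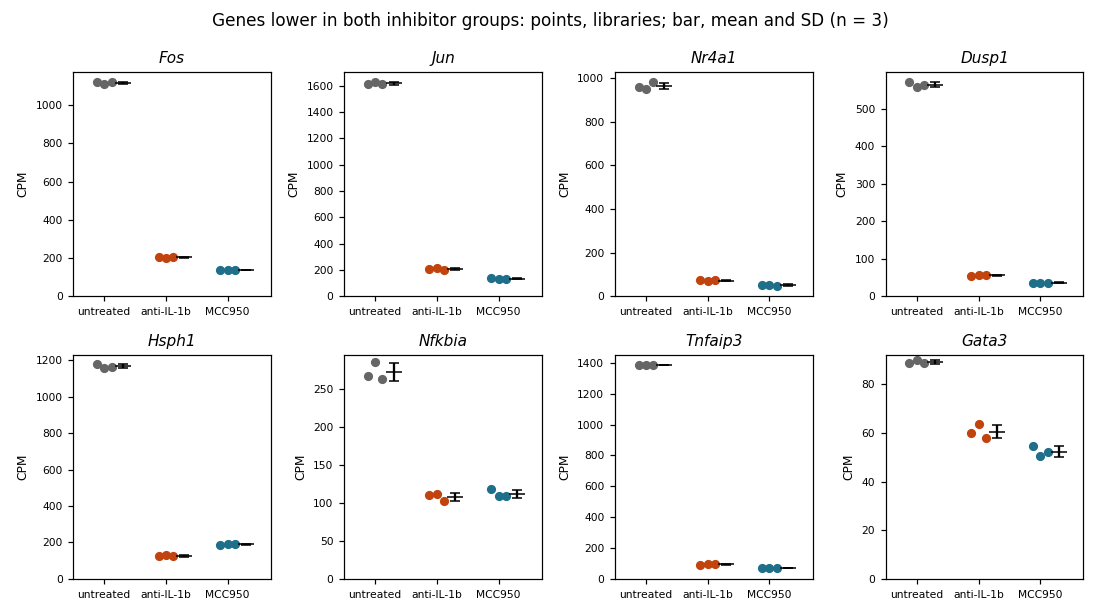
CPM (linear axes from 0) of Fos, Jun, Nr4a1, Dusp1, Hsph1, Nfkbia, Tnfaip3 and Gata3 in each library of the untreated, anti-IL-1b and MCC950 groups; points are libraries, and bars give the mean and SD of 3. In every panel the 6 libraries of the inhibitor groups lie below the 3 untreated ones, for Fos at means of 205 and 138 CPM against 1117.

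Genes of quiescence and of glucocorticoid and stress responses were lower with the antibody, and interferon genes were slightly higher. Of the 13 tested glucocorticoid response genes, 10 fell and 1 rose, with a median log2 fold change of -1.16 (10 and 2 adjusted over the list alone; camera adjusted p = 5.16e-10). Cxcr4, a chemokine receptor gene, fell from 372 ± 1.1 to 31.9 ± 1.90 CPM, and the circadian gene Per1 from 279 ± 14.4 to 43.2 ± 4.92 CPM. Tsc22d3, the leucine zipper gene GILZ, fell from 414 ± 6.06 to 219 ± 8.65 CPM and Dusp1, a MAP kinase phosphatase gene, from 565 ± 6.0 to 56.2 ± 1.65 CPM. The naive and quiescence list had 13 members lower and 4 higher of 22 (14 and 5 adjusted over the list alone; camera adjusted p = 3.81e-05), with a median of -0.10 that turned to 0.03 under library totals. The antiproliferative genes Btg1, Btg2 and Tob1 had log2 fold changes of -1.07, -1.54 and -1.85. Klf2, a transcription factor gene that keeps T cells quiescent and recirculating, fell from 969 ± 19.5 to 390 ± 10.0 CPM. Of the 15 TGF-beta response genes, 9 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.32, camera adjusted p = 6.07e-04). Within that list Tgif1 and Smad7 had log2 fold changes of -2.09 and -0.96. Cdkn1a, the cell cycle inhibitor gene p21, fell by 5.19 from 5.57 ± 0.293 CPM, whereas Itgae, an integrin gene, rose by 3.24. Among amino acid stress response genes 9 of 18 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.18, camera adjusted p = 6.07e-04). The leading members were Atf4 at -1.32, Cebpb at -2.65, Slc3a2 at -0.63 and Ddit4 at -0.51. Ribosome biogenesis genes fell in 15 of 33 cases and rose in 2 (15 and 4 adjusted over the list alone; camera adjusted p = 0.00137), with a median of -0.12 that became 0.01 under library totals. Odc1, Hspd1, Hspe1 and Ncl changed by -1.91, -1.39, -1.29 and -0.29, and Hspd1 and Hspe1 are also heat shock genes. Type I interferon response genes went the other way, with 16 of 39 higher and 2 lower (17 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 4.06e-04). Among them Ifi27l2a, Lgals3bp, Stat2 and Zbp1 rose by 0.56, 0.54, 0.39 and 0.33.

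Helper subset genes of the type 2 and type 17 lists were lower with the antibody under the preset correlation. Gata3, the lineage factor gene of type 2 helper cells, which naive CD4+ cells also express (chromosome 2, 9857078 to 9890034), fell from 89.2 ± 0.845 to 60.5 ± 2.79 CPM. Maf, Il4ra and Ccr8 had log2 fold changes of -0.75, -0.28 and -3.38, of which the Il4ra call was lost with TPM. In the type 2 list 5 of 7 members fell and 1 rose (5 and 1 adjusted over the list alone; median -0.28, camera adjusted p = 0.0178). That call was lost with an estimated correlation, at camera adjusted p = 0.307, the highest value over 17 settings. The lowest, 6.55e-04, came from fry, which does not compare a list with other genes. In the type 17 list 3 of 7 fell (3 adjusted over the list alone; median -0.24, camera adjusted p = 0.0321; adjusted p = 0.101 with an estimated correlation). Irf4 changed by -3.38, Batf by -0.70 and Stat3 by -0.24, while Rora, at -0.26 ± 0.16, did not pass. The Stat3 call was lost with TPM, where its log2 fold change was -0.12. The list of IL-1 and inflammasome components did not pass (camera adjusted p = 0.517). Its mean log2 fold change of 0.50 and median of -0.20 differ in sign, with Il1b higher and 6 of 15 members lower. Casp1 fell by 0.90 and lost its call without untreated replicate 2, where the log2 fold change was -0.73, and with TPM.

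Markers of other cell types were higher in the antibody group, and the labels name no sort or gate for the cells. Of 21 tested B cell markers 20 rose (20 adjusted over the list alone; median 2.39, camera adjusted p = 2.93e-15). Cd74, the invariant chain gene of antigen-presenting cells (chromosome 18, 60803848 to 60812652), rose from 9.98 ± 2.34 to 38.6 ± 0.806 CPM. Cd22 went from 1.11 ± 0.459 to 5.08 ± 1.17 CPM, a call lost with TPM, and the MHC class II genes H2-Aa and H2-Eb1 rose by 2.44 and 2.39 on the log2 scale. Syk, a kinase gene of B cell and myeloid receptors (chromosome 13, 52583173 to 52648792), rose from 0.542 ± 0.0598 to 5.99 ± 0.119 CPM. Cytotoxic and NK markers rose in 6 of 11 cases and fell in 1 (8 and 1 adjusted over the list alone; median 0.88, camera adjusted p = 0.00172). Cd8a gave the largest change among them, 4.33 ± 0.19 on the log2 scale (chromosome 6, 71373427 to 71379173). Cd8b1 rose as well, from a higher untreated level, from 12.5 ± 1.83 to 26.2 ± 0.764 CPM. Neutrophil and granulocyte markers rose in 9 of 10 cases (9 adjusted over the list alone; median 6.63, or 6.05 with members at 0 in untreated cells set to their bound; camera adjusted p = 3.81e-09). Csf3r, the receptor gene of a granulocyte growth factor, rose from 0.0679 ± 0.0588 to 6.09 ± 1.08 CPM. Of the 19 neutrophil markers 10 were tested, and those with such low untreated levels could enter only through an inhibitor group. Markers of monocytes, macrophages and dendritic cells rose in 6 of 13 cases (6 adjusted over the list alone; median 0.90, camera adjusted p = 0.00599; adjusted p = 0.0771 with an estimated correlation). Lyz2 went from 0.845 ± 0.0495 to 6.93 ± 1.22 CPM. Red cell markers rose in 5 of 7 cases (5 adjusted over the list alone; median 3.19, or 3.0 with bounds; camera adjusted p = 0.0184; adjusted p = 0.0877 with an estimated correlation). Their most significant member, the beta-globin gene Hbb-bs, had 0 counts in untreated cells and 1.99 ± 0.315 CPM with the antibody. That level was 36.9-fold above the untreated floor of 3 counts. Hbb-bt, the near-identical neighbour of Hbb-bs, may share reads with it.

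Cytosolic ribosomal protein genes fell in 73 of 78 cases with the antibody, with a median of -0.19 (74 adjusted over the list alone; camera adjusted p = 4.22e-31). Library totals moved the median of all genes up by 0.127, so the size of this fall depended on the scaling. These genes held 9.48 ± 0.0812% of the counts in untreated and 9.08 ± 0.0615% in anti-IL-1b libraries. Rps14 changed by -0.32, and its processed pseudogenes may share its reads. Mitochondrially encoded genes fell in 3 of 13 cases (3 adjusted over the list alone; camera adjusted p = 0.0345; adjusted p = 0.402 with an estimated correlation), with a median of -0.06 that turned to 0.07 under library totals. Of these, mt-Nd2 had a log2 fold change of -0.27. Several lists did not pass in this comparison, among them those of cell cycle genes (camera adjusted p = 0.517), regulatory T cells (0.517), activated and memory T cells (0.517), type 1 helper cells (0.768), follicular helper cells (0.968), interferon gamma response (0.787), STAT3 and STAT5 response (0.198), cytokine receptors (0.0877), glycolysis (0.555), oxidative phosphorylation (0.787), cholesterol synthesis (0.768), plasma cells (0.350) and thymocytes (0.345). Single genes on these lists still changed. Ctla4, an inhibitory receptor gene of regulatory and activated T cells, fell from 43.9 ± 1.83 to 3.08 ± 0.964 CPM, and Pcna, a replication clamp gene, from 201 ± 1.59 to 107 ± 2.34 CPM. Pim1 fell from 271 ± 1.13 to 129 ± 7.66 CPM, Ifngr1 from 180 ± 5.98 to 95.6 ± 3.07 CPM, and Irf1 from 473 ± 7.11 to 269 ± 7.0 CPM. Insig1 fell from 102 ± 5.43 to 40.7 ± 4.93 CPM, and Xbp1 from 60.0 ± 2.19 to 32.5 ± 3.01 CPM. Icos fell from 48.8 ± 2.33 to 32.0 ± 3.13 CPM, Fasl from 14.5 ± 1.13 to 4.10 ± 0.581 CPM and Runx3 from 118 ± 2.07 to 79.2 ± 4.33 CPM. Pdk1, a kinase gene that limits pyruvate oxidation, rose from 302 ± 8.48 to 483 ± 9.90 CPM.

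MCC950 gave much the same picture when compared with untreated cells, with larger falls of Fosb and Klf4. Fosb (chromosome 7, 19302696 to 19310051) fell from 687 ± 16.2 to 12 ± 1.42 CPM, a log2 fold change of -5.84 ± 0.05 (adjusted p = 1.76e-45). Klf4, a transcription factor gene, fell from 59.2 ± 1.52 to 1.37 ± 0.357 CPM, at -5.43 ± 0.15 (adjusted p = 8.22e-29). Tnfaip3 fell from 1387 ± 0.679 to 70.8 ± 1.67 CPM, at -4.29 ± 0.03 (adjusted p = 1.47e-46). Cd8a rose from 0.970 ± 0.270 to 19.7 ± 1.07 CPM, at 4.35 ± 0.19 (adjusted p = 1.46e-21). In all, 4921 genes passed, 2369 higher and 2552 lower with MCC950, and 760 of them differed at least 2-fold. The split became 2859 higher and 2211 lower with upper-quartile scaling, 4009 and 1587 with library totals, which moved the median of all genes by 0.11, and 2169 and 1094 with TPM, where the count itself dropped to 3263.

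Beyond Fosb and Klf4, the largest falls with MCC950 among named genes with a mean log2 CPM of at least 2 were those of Maff, Nr4a2, Gem, Sik1, Dusp4 and Tnfaip3, with log2 fold changes of -5.04, -4.84, -4.62, -4.46, -4.38 and -4.29. The T cell receptor response list had 17 of 25 members lower and 6 higher (17 and 6 adjusted over the list alone; median -1.26, camera adjusted p = 1.57e-13, and 6.88e-05 without the members shared with the heat shock list). Nr4a1 stood at 50.9 ± 3.70 CPM, Jun at 133 ± 4.66 CPM and Fos at 138 ± 2.02 CPM after MCC950. Of the NF-kB list 11 of 19 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.22, camera adjusted p = 1.88e-07). Nfkbid, Nfkbiz and Nfkbia changed by -2.09, -1.46 and -1.28. All 22 heat shock and handling stress genes fell, as with the antibody (22 adjusted over the list alone; median -2.04, camera adjusted p = 5.18e-52). Glucocorticoid response genes fell in 9 of 13 cases and rose in 1 (9 and 1 adjusted over the list alone; median -1.01, camera adjusted p = 3.36e-10). Cxcr4 stood at 31.6 ± 1.68, Dusp1 at 36.2 ± 0.757, Per1 at 44.4 ± 2.44 and Tsc22d3 at 206 ± 4.30 CPM. The naive and quiescence list had 16 of 22 members lower and 2 higher (16 and 2 adjusted over the list alone; median -0.22, camera adjusted p = 3.62e-11). Klf2, Btg2, Btg1 and Tob1 changed by -1.44, -1.39, -1.13 and -1.81, and Ccr7 by -0.55. TGF-beta response genes fell in 10 of 15 cases and rose in 2 (10 and 2 adjusted over the list alone; median -0.34, camera adjusted p = 4.76e-04). Tgif1, Smad7, Skil and Cdkn1a changed by -2.41, -0.87, -0.39 and -5.81.

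With MCC950, type I interferon response genes rose in 21 of 39 cases and fell in 2 (23 and 2 adjusted over the list alone; median 0.25, camera adjusted p = 3.50e-05). Ifit1 went from 14.3 ± 2.08 to 27.9 ± 1.31 CPM, Ly6a from 63.3 ± 2.61 to 86.4 ± 3.47 CPM, and Ifi27l2a and Lgals3bp rose by 0.56 and 0.55. Nuclear-encoded oxidative phosphorylation genes rose in 24 of 68 cases and fell in 1 (24 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 6.88e-05; adjusted p = 0.0840 with an estimated correlation). Ndufb7, Atp5e and Atp5h, which encode parts of complex I and of the ATP synthase, rose by 0.47, 0.35 and 0.32, and Cycs, the cytochrome c gene, was the member that fell, by 0.42, a call lost with TPM. Mitochondrially encoded genes moved the other way, with 8 of 13 lower (8 adjusted over the list alone; median -0.41, camera adjusted p = 2.18e-08; adjusted p = 0.0560 with an estimated correlation). Transcripts of mt-Nd2 fell from 1153 ± 18.1 to 706 ± 13.4 CPM. Type 2 helper genes fell in 5 of 7 cases and rose in 1 (5 and 1 adjusted over the list alone; median -0.47, camera adjusted p = 0.0121; adjusted p = 0.251 with an estimated correlation). Gata3 fell to 52.3 ± 2.16 CPM and Maf from 15 ± 0.348 to 6.13 ± 0.795 CPM. Il4ra and Stat6 changed by -0.12 and -0.17, calls that scaling to library totals or the use of TPM ended. Type 17 genes fell in 4 of 7 cases (5 adjusted over the list alone; median -0.50, camera adjusted p = 0.0195; adjusted p = 0.0840 with an estimated correlation). Irf4, Batf and Stat3 changed by -3.48, -0.55 and -0.27, and Rora by -0.50, which lost its call without MCC950 replicate 1 at a log2 fold change of -0.38, and with TPM.

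Markers of other cell types were higher with MCC950 as well. B cell markers rose in 20 of 21 cases (20 adjusted over the list alone; median 2.53, camera adjusted p = 1.21e-13). Cd74 stood at 43.6 ± 4.30, Cd22 at 6.55 ± 0.863, H2-Aa at 13.8 ± 1.2 and H2-Ab1 at 13.6 ± 3.55 CPM, and the Cd22 call was lost with TPM. Cytotoxic and NK markers rose in 5 of 11 cases (6 adjusted over the list alone; median 0.96, camera adjusted p = 9.33e-04). Neutrophil markers rose in 8 of 10 (8 adjusted over the list alone; median 5.79, or 5.48 with bounds; camera adjusted p = 6.80e-06). Markers of monocytes, macrophages and dendritic cells rose in 8 of 13 (8 adjusted over the list alone; median 1.22, camera adjusted p = 6.34e-04). Red cell markers rose in 4 of 7 (4 adjusted over the list alone; median 3.50, camera adjusted p = 0.0155; adjusted p = 0.0840 with an estimated correlation). Csf3r reached 3.92 ± 1.06 CPM, Lyz2 7.26 ± 1.28 CPM and Syk 5.45 ± 1.35 CPM. Tnfrsf9 reached 5.05 ± 0.442 CPM and Hbb-bs 3.45 ± 0.760 CPM, the latter 64.1-fold above the untreated floor of 3 counts. Cytosolic ribosomal protein genes fell in 40 of 78 cases and rose in 7 (42 and 8 adjusted over the list alone; camera adjusted p = 1.33e-05; adjusted p = 0.302 with an estimated correlation), with a median of -0.07 that turned to 0.04 under library totals. Rpl17, whose reads its pseudogenes may share, changed by -0.35. The lists of IL-1 and inflammasome components (camera adjusted p = 0.492), ribosome biogenesis (0.247), amino acid stress (0.1), cholesterol synthesis (0.0563), cell cycle (0.247) and regulatory T cells (0.372) did not pass. Neither did those of activated and memory T cells (camera adjusted p = 0.579), type 1 helper cells (0.938), follicular helper cells (0.621), interferon gamma response (0.799), STAT3 and STAT5 response (0.131), cytokine receptors (0.112), glycolysis (0.408), plasma cells (0.393) and thymocytes (0.548). Single members passed. Casp1 fell by 1.77, Atf4 by 1.19, Insig1 by 1.26, Hspd1 by 1.16, Pcna by 0.72, Ctla4 by 3.81 and Itga4, an integrin gene, by 0.58. Cd44 fell by 0.30, and its call was lost without untreated replicate 2 (-0.27) or MCC950 replicate 3 (-0.21). It was also lost under library totals (-0.19), with TPM (-0.20) and after removal of GC and length trends (-0.24). Foxp3 rose by 1.54 from its low level, and its call was lost without any of untreated replicates 2 and 3 and MCC950 replicates 1 and 2 (1.24, 1.39, 1.14 and 1.64), and with TPM.

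**Figure D2:**
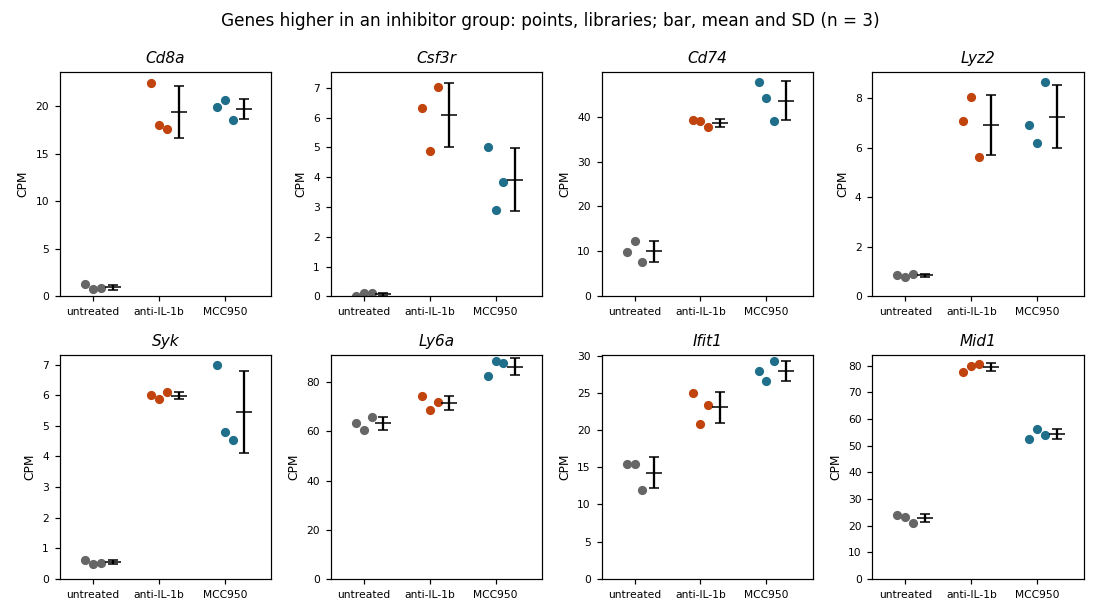
CPM (linear axes from 0) of Cd8a, Csf3r, Cd74, Lyz2, Syk, Ly6a, Ifit1 and Mid1 in each library of the untreated, anti-IL-1b and MCC950 groups; points are libraries, and bars give the mean and SD of 3. In every panel the 6 libraries of the inhibitor groups lie above the 3 untreated ones, for Cd8a at means of 19.4 and 19.7 CPM against 0.970; Mid1 was chosen after its values were seen.

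The changes under the 2 agents were closely related across genes. Of the 4545 and 4921 genes that passed in each comparison with untreated cells, 3190 changed the same way in both, 1406 up and 1784 down, and 53 changed in opposite directions. Independent lists of these sizes would share 366 genes up and 473 down. In 20 simulations all 9 libraries were drawn anew from the untreated means, and the 2 comparisons shared 0 genes. With no gene changed almost none pass, so that 0 cannot show how much overlap comes from shared controls. The log2 fold changes correlated across the 13374 genes with Pearson r = 0.856 and Spearman rho = 0.744, against a simulated r of 0.487 ± 0.0192 for unchanged groups with shared controls, and genes are not independent replicates. The covariance was 0.546, against 0.0466 in the simulations, a difference of 0.499, and 78.4% of genes had the same sign against 66.4% simulated. The simulated libraries held no shift of the untreated group as a whole, which would move both comparisons alike. How much of the excess comes from the shared untreated libraries therefore stays open. These libraries, at 3, could not be divided into groups of at least 2.

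**Figure D3:**
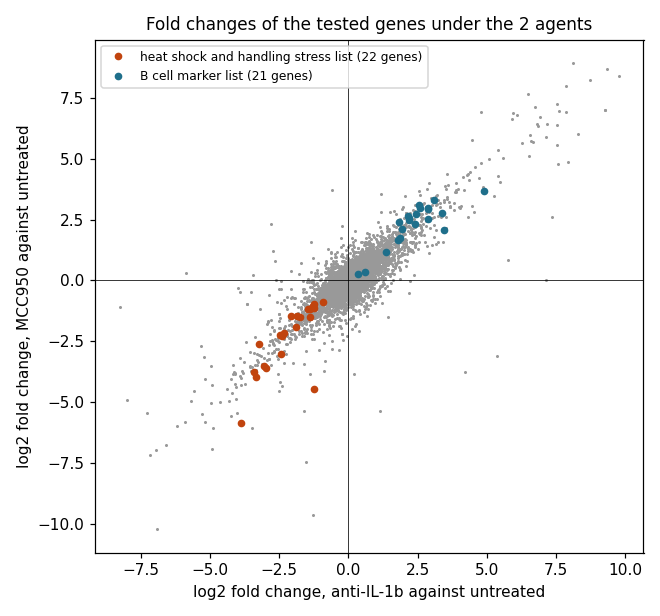
Log2 fold change of each of the 13374 tested genes against untreated cells, with the antibody on the x axis and MCC950 on the y axis (both log2 scales); grey points are genes, red points the 22 heat shock and handling stress genes and blue points the 21 tested B cell markers. The red points all lie below 0 and the blue points all lie above 0 on both axes, and Pearson r over all genes is 0.856.

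Set against each other, the antibody and MCC950 groups differed in individual genes and in a few gene groups, and most differences were small. Eps8l1, which encodes a relative of the actin regulator EPS8 (chromosome 7, 4460674 to 4480487), was at 2.21 ± 0.503 CPM with the antibody and 74.8 ± 1.96 with MCC950, a log2 difference of -5.09 ± 0.13 (adjusted p = 3.97e-28). Slc15a2, a peptide transporter gene (chromosome 16, 36750177 to 36784962), was at 2.58 ± 0.250 against 40.2 ± 1.23 CPM, at -3.96 ± 0.14 (adjusted p = 5.78e-23). Exosc6, an RNA exosome gene, was lower with the antibody by 3.67, and Gdpd3 and the interferon gene Isg15 had log2 differences of -1.19 and -0.91, of which the Gdpd3 call was lost with limma-voom. Acvrl1, a TGF-beta family receptor gene, was higher with the antibody, at 21.7 ± 4.70 against 1.29 ± 0.628 CPM, a log2 difference of 4.07 ± 0.22 (adjusted p = 1.49e-13), as were Fosb by 1.94, Xlr3b by 1.72 and Klf4 by 1.40. Xlr3b (chromosome X, 73192207 to 73202930) has near-identical neighbours that may share its reads. In all, 1771 genes passed, 820 higher and 951 lower with the antibody, of which 78 differed at least 2-fold. With TPM 572 passed, 363 higher and 209 lower, and with library totals the split was 938 and 818.

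Naive T cell genes were higher with the antibody than with MCC950, and ribosome biogenesis genes were lower. In the naive and quiescence list 11 of 22 members were higher and 3 lower (13 and 3 adjusted over the list alone; median 0.09, camera adjusted p = 8.63e-07). Il7r and Klf2 were higher by 0.21 and 0.13. Cd4 was higher by 0.13 and Gata3 by 0.21, the latter losing its call without anti-IL-1b replicate 2 (0.17) or MCC950 replicates 2 (0.18) or 3 (0.21). Ribosome biogenesis genes were lower in 13 of 33 cases with none higher (15 adjusted over the list alone; median -0.12, camera adjusted p = 6.66e-05). These 2 lists were the biology lists whose calls held with an estimated correlation. Oxidative phosphorylation genes were lower in 20 of 68 cases (24 adjusted over the list alone; median -0.13, camera adjusted p = 1.87e-08; adjusted p = 0.0606 with an estimated correlation). Cholesterol synthesis genes were lower in 4 of 21 (5 adjusted over the list alone; median -0.13, camera adjusted p = 0.0125; adjusted p = 0.0955 with an estimated correlation) and amino acid stress genes in 5 of 18 (6 adjusted over the list alone; median -0.13, camera adjusted p = 0.00171; adjusted p = 0.0606 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 52 of 78 cases and higher in 1 (59 and 1 adjusted over the list alone; median -0.11, camera adjusted p = 1.11e-30; adjusted p = 0.0659 with an estimated correlation). Mitochondrially encoded genes were higher in 8 of 13 (9 adjusted over the list alone; median 0.30, camera adjusted p = 2.23e-14; adjusted p = 0.0595 with an estimated correlation).

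The T cell receptor response list was higher with the antibody than with MCC950 in 6 of 25 cases and lower in 5 (7 and 5 adjusted over the list alone; median 0.11, camera adjusted p = 0.0302; adjusted p = 0.333 with an estimated correlation). Nr4a1, Fos and Jun were higher by 0.50, 0.57 and 0.63. Its call rested on the members shared with the heat shock list, without which adjusted p was 0.961 and the direction turned. It was also lost without anti-IL-1b replicate 1 or 2. Over the settings tried the highest adjusted p was the 0.961 from camera. The lowest, 0.00256, came from fry, which does not compare a list with other genes. Heat shock and handling stress genes went both ways, 7 higher and 12 lower of 22 (7 and 12 adjusted over the list alone; camera adjusted p = 0.241), with a median of -0.12 and a mean of 0.20 that differ in sign. Hsph1 was lower with the antibody by 0.59. Glycolysis genes were lower in 6 of 22 cases and higher in 1 (6 and 1 adjusted over the list alone; median -0.11, camera adjusted p = 0.0302; adjusted p = 0.325 with an estimated correlation). That call was lost without anti-IL-1b replicate 1 or 3 or MCC950 replicate 1. Neutrophil markers were higher with the antibody in 2 of 10 cases (4 adjusted over the list alone; median 0.79, camera adjusted p = 0.00755; adjusted p = 0.130 with an estimated correlation). Il1b, which neutrophils and monocytes also express, was higher by 1.37 ± 0.31 (adjusted p = 0.00205). The B cell list did not pass between the agents (camera adjusted p = 0.930). Casp1 was higher with the antibody by 0.87. The call was lost without any one of anti-IL-1b replicates 1 and 2 and the MCC950 replicates, where the difference ranged from 0.70 to 0.93. It was also lost with limma-voom (0.87), TPM (0.76) and a fit of 6 samples (0.87). Removal of GC and length trends (0.81) and division of counts by the variance-to-mean factor (0.91) ended it too, with the difference little changed.

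When the 6 libraries of both inhibitor groups were set against the 3 untreated ones, genes that fell under each agent were lower. This follows from the use of the same libraries and is no independent support. Maff fell by 5.0, Klf4 by 4.60, Fosb by 4.59, Bambi by 4.56 and Sik1 by 4.43 on the log2 scale, and Cd8a, Syk, Lyz2 and Tnfrsf9 rose by 4.34, 3.39, 3.06 and 2.73. In all, 4189 genes passed, 1956 higher and 2233 lower, and 754 of them differed at least 2-fold. The split was 2541 and 1809 with upper-quartile scaling, 3787 and 1240 with library totals, which moved the median by 0.12, and 2426 and 878 with TPM. Of the 22 biology lists tested, 11 passed, and 5 did so with an estimated correlation: NF-kB, T cell receptor, TGF-beta and glucocorticoid response genes, which fell, and type I interferon response genes, which rose. Their adjusted p-values from camera were 1.26e-07, 8.24e-11, 3.37e-04, 3.99e-09 and 7.53e-05, with 11 of 19, 17 of 25, 9 of 15 and 9 of 13 members lower (14, 17, 9 and 9 adjusted over the list alone) and 15 of 39 higher (17 adjusted over the list alone). The naive and quiescence list, the type 2 and type 17 lists, amino acid stress, ribosome biogenesis and oxidative phosphorylation genes passed with the preset correlation alone (adjusted p = 0.137, 0.184, 0.0823, 0.362, 0.465 and 0.595 with an estimated correlation). The ribosome biogenesis call was also lost under library totals, without anti-IL-1b replicate 3, and without the 2 members shared with the heat shock list (camera adjusted p = 0.193), and the oxidative phosphorylation call without untreated replicate 1 or any MCC950 replicate. B cell markers rose in 20 of 21 cases (20 adjusted over the list alone; camera adjusted p = 1.24e-16), and heat shock and handling stress genes fell in 21 of 22 (22 adjusted over the list alone; camera adjusted p = 3.62e-35).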

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

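The test of other splits of the libraries was planned before the data were examined. The removal of GC and length trends was added after the data were seen, and all other tests of explanations here were chosen only after the result was seen. Among all genes tested, 53 passed in both comparisons with untreated cells and changed in opposite directions. Of the genes named by rule, 3 did so, each with a direct test of the difference by edgeR's quasi-likelihood test. Eps8l1 fell with the antibody (-2.79) and rose with MCC950 (2.30), a difference of -5.09 (adjusted p = 3.97e-28). Slc15a2 fell by 2.73 with the antibody and rose by 1.23 with MCC950, a difference of -3.96 (adjusted p = 5.78e-23). Xlr3b rose by 0.62 with the antibody and fell by 1.1 with MCC950, a difference of 1.72 (adjusted p = 8.86e-14). Groups of 3 libraries were not tested for single libraries far from the others.

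Replicates of a group lay close together. The lowest chi-square per degree of freedom among the 9 pairs of replicates was 2.84, which argues against 1 library having been read again. Variance-to-mean factors of genes with 300 to 1000 and with 10 to 100 counts differed by at most 1.1 times, which is what libraries made from 1 RNA pool per group would give. Above 10000 counts the factors were 22.3, 15.9 and 25.3 in the untreated, anti-IL-1b and MCC950 groups, so an added spread between libraries was present there. Whether the replicates are separate mice stays open.

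The 22 heat shock and handling stress genes were lower in both inhibitor groups. Removal of GC and length trends left a median log2 fold change of -1.95 or lower, which argues against those trends as the cause. The median nearest to 0 under 4 scalings was -1.85. Library totals moved the median of all genes by 0.127 with the antibody, so a choice among these scalings could not remove such a fall. Of the lists of other cell markers, 0 were lower in an inhibitor group by camera or fry, at an adjusted or an unadjusted p under 0.05, since the direction of each was up, which argues against other cells among the untreated cells. The 11 chaperone genes of the list had medians of -1.85 with the antibody and -1.47 with MCC950. Handling of the cells before lysis that differed between the groups may give such a fall. It cannot be told apart from an effect of the agents, which stays open and untested, because handling, if it differed, followed the groups. The other lists that fell against untreated cells share this limit.

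Markers of other cell types were higher in both inhibitor groups. At least 80% of tested B cell and neutrophil markers rose in either comparison with untreated cells. That share restates the pattern, so it cannot decide whether other cells were among the isolated cells, which stays open. Only 10 of 19 neutrophil markers were tested, at a median of 0.0247 CPM in untreated cells. Many of them could therefore enter the test only through an inhibitor group. Abundant transcripts of such cells stayed low, with Igkc at 1.1 ± 0.162, 8.23 ± 0.720 and 8.62 ± 1.62 CPM in the untreated, anti-IL-1b and MCC950 groups and S100a8, at 0 counts in untreated cells, at 3.03 ± 1.08 and 2.14 ± 0.313 CPM, genes named after their values were seen. In untreated cells 10 of 21 B cell markers and 2 of 10 neutrophil markers lay at 1 CPM or more, and 1 B cell marker is on another list. The labels name no sort or gate, and a change in the cells of the spleen under the agents stays open as untested.

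Other splits of the libraries were counted for each number of changed genes. The 10 splits of 6 libraries are too few for a share under 0.05. The real values were 4545, 4921 and 1771 genes for anti-IL-1b against untreated, MCC950 against untreated and the agents against each other, and the highest other split gave 1 gene in each, so that 1 of 10 splits reached the real value. For either inhibitor against untreated, 1 of 84 splits, the real one, reached 4189 genes. The highest other split, with the MCC950 libraries as the 3, gave 404 genes, and the next, with the anti-IL-1b libraries, gave 138. These 3 splits alone keep the groups whole, and whether the libraries of a group are separate mice stays open, so the count of 84 does not exclude chance between groups.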

How the results depend on the processing

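The removal of GC and length trends, the test against a fold of 1.5, the division of counts and the removal of stress genes from other lists were tests chosen after the result was seen. Numbers of changed genes are given in the order anti-IL-1b against untreated, MCC950 against untreated, the agents against each other and either inhibitor against untreated. They fell to 818, 760, 78 and 754 with a log2 fold change of at least 1 and to 609, 587, 21 and 559 in the test against a fold of 1.5, both of which ask for larger changes. With TPM, MCC950 against untreated gave 3263 genes, 2720 of them shared with the counts, and the agents 572, of which 490 were shared, and the cause was not tested. All other settings left these counts within 1.5 times. The correlation of fold changes was 0.594 with no filter beyond 1 count, where more genes of few counts enter. Lists called numbered 17 for MCC950 with fry, which does not compare a list with other genes, and 2 between the agents and 5 for either inhibitor with an estimated correlation. Cd4 with MCC950 reversed to 0.0677 under library totals, which shift all genes upward. Without single libraries, genes changed ranged from 3954 to 4498, 4201 to 5021, 1246 to 1763 and 3237 to 4328, the correlation from 0.785 to 0.859, genes changed alike from 2813 to 3075, and lists from 10 to 10, 9 to 10, 5 to 7 and 10 to 11. Of 2862 values of named genes under other settings 2774 kept their side of the threshold, 74 lost the call, 13 gained one and 1 reversed, and of 1728 without single libraries 1708 kept their side. In each of these sets 6 values that had not passed changed sign.

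Residual correlations were -0.00967 to 0.0625 for libraries of the same replicate number and -0.0573 to 0.0252 for others. Of 18 best matches 16 shared the number, so the data hint that libraries were linked by number. The labels name no such link, and the main fit leaves it out. With the replicate block 4483, 4855, 1704 and 3782 genes changed, the correlation was 0.853, 3129 genes changed alike and 10, 9, 7 and 11 lists passed. Among named genes the block added the call of Foxp3 for either inhibitor against untreated and changed no other. Genes near 1 CPM had few counts at this depth, such as Foxp3 with 29, 56 and 84 over the untreated, anti-IL-1b and MCC950 libraries, and no test varied the depth.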

Other observations

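The genes in this part were chosen after their values were seen, and their comparisons are the planned ones. Neighbouring genes near the end of chromosome X were far higher in both inhibitor groups. Mid1, a ubiquitin ligase gene (chromosome X, 169685199 to 170005736), stood at 22.7 ± 1.5, 79.5 ± 1.65 and 54.3 ± 1.90 CPM in the untreated, anti-IL-1b and MCC950 groups. G530011O06Rik, which lies within the Mid1 interval (169975043 to 169978917), stood at 0.630 ± 0.0489, 147 ± 13.1 and 75.6 ± 2.66 CPM. Its neighbour Gm21887 (170009659 to 170019281) stood at 13.1 ± 5.76, 44.6 ± 3.56 and 31.3 ± 4.92 CPM. On chromosome Y, Gm47283 (90784738 to 90816464) stood at 59.5 ± 9.01, 213 ± 7.95 and 102 ± 18.3 CPM. Whether the mice of the groups differed at these genes apart from the agents was not tested. Values of overlapping genes are uncertain, since the use of strand is not given.

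Cell cycle genes did not move as 1 group. Mki67 and Top2a, genes of dividing cells, rose with the antibody by 1.07 and 1.44 and with MCC950 by 0.97 and 1.36, while Pcna had log2 fold changes of -0.91 and -0.72. Pycard, the inflammasome adaptor gene, rose from 47.1 ± 1.78 to 61.1 ± 2.44 CPM with the antibody and to 66.3 ± 1.91 CPM with MCC950. Irak3, an inhibitor of IL-1 receptor signalling, had log2 fold changes of -0.80 and -1.15.

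Processed pseudogenes were among the strongly changed genes more often than protein-coding genes, with no test of that difference. With the antibody 48 of 444 (10.8%) differed at least 2-fold past the threshold, against 533 of 11154 (4.78%) protein-coding genes, and with MCC950 48 of 444 against 507 (4.55%). The pseudogene Gm8730 (chromosome 8, 102864845 to 102865798) fell from 245 ± 5.29 to 4.07 ± 0.376 and 4.36 ± 0.240 CPM. Pseudogenes may share reads with the genes they resemble, so these values are uncertain, and the cause was not tested.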
